A study of Mus musculus with 3 samples.

How the data were processed

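The data are 3 libraries of single cells from mouse hearts, made with droplet-based 3′ chemistry (10x Chromium, v2) and named in the labels as steady-state macrophages, macrophages at day 11 after infarction, and steady-state macrophages with dendritic cells. Each group has 1 library, and the labels do not say how many animals were pooled in each. The deposited values are raw counts, that is UMI counts per gene and cell barcode, made per the submitters' processing notes with Cell Ranger and STAR on the mm10 build. The versions of these tools are not given in the sources used here. The cell barcodes had been called by the authors, and the calling rule is not stated. The 3 tables share 27998 genes, and the libraries from the reporter mice hold 3 further entries, TdTomato, CreERT2 and EYFP. Gene positions came from the GENCODE vM21 annotation of mm10. No filter on values was found in the tables, which hold whole numbers with different totals per library.

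Cells were kept with at least 500 detected genes and at most 10% of UMIs from mitochondrial genes. This removed 39 barcodes of the steady-state macrophage library, 24 of the day 11 library and 13 of the macrophage and DC library. Doublets were scored with Scrublet in each library, and the barcodes with the highest scores were removed, in number 0.8% per 1000 barcodes: 26, 176 and 25 barcodes. The automatic threshold of Scrublet would have marked 7, 0 and 2 barcodes. With 4673 barcodes scored and none marked, that threshold did not work for the day 11 library. Removal by number leaves some doublets in. Shared barcodes between libraries were about as many as chance gives, 8 for the steady-state and day 11 macrophage libraries where 11.5 were due.

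Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen with the library as batch, leaving out mitochondrial, ribosomal protein, sex-linked and reporter entries. All libraries were clustered together without integration on 30 principal components, 15 neighbours and the Leiden method at resolution 1.0, which gave 25 clusters. Clusters were named from 22 fixed marker lists when at least 3 of their 10 top genes were markers of 1 class, and 17 clusters were named. A cycling cluster was set with the DCs when the median log2 fold of a DC marker list over the other cells was above 0.5. The marker lists were fixed before the data were examined, and details of the naming rule were coded after the data had been seen. Class names carry "-like" because they rest on RNA alone. Clusters of DCs, lymphoid cells, endothelial cells and fibroblasts were set outside the macrophage compartment. Monocytes and cycling macrophages stayed inside it. So did clusters 0, 2, 3, 5, 6, 12 and 16, which met no marker rule and entered it by default.

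UMIs were summed over the cells of a library and class and divided by the total of non-reporter UMIs to give CPM. Ratios have exact 95% intervals from the UMI counts, and shares of cells have exact Clopper-Pearson 95% intervals. All intervals cover counting error only, and no p-value is given because each group has 1 library. Intervals of ratios treat each UMI as independent, so differences between the cells of a class are left out. A count of 0 was replaced by 3 counts to bound a ratio, and a share of 0 is given with its exact upper bound. The macrophages of the macrophage and DC library, that is all cells of its compartment, served as a second steady-state reference. That library differs in genotype and gate, so its distance from the first is a yardstick and not a replicate error.

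Genes were named by a rule fixed before the data were examined. For the compartment, these were genes with at least 50 CPM in either library that differed at least 2-fold in the same direction from both references, and the 15 with the largest smaller fold in each direction were taken. Within a class the rule took 10 genes in each direction, against the second reference only where it had at least 30 cells of the class. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, sex-linked and unnamed genes were not named by it. Members of the 26 fixed gene lists and the markers may be named besides. A list's value is the median log2 ratio of its members with at least 20 CPM in either library, set against 10000 random lists of the same size matched on expression. This percentile describes these libraries and is not a test across animals.

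For shares of cells with a UMI, cells were thinned to 3000 UMIs, and 0, 84 and 172 compartment and other cells below that number were left out. A cycling cell had UMIs of at least 3 of 25 cell cycle genes. The background of each share was read in DC-like and lymphoid cells and in endothelial-like cells of the same library. Reporter shares used all UMIs.

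The procedure was tested on simulated data before use, with 5169 genes above the list minimum. All 50 genes raised 4-fold and all 50 lowered 4-fold were called at least 2-fold different from both references. Of genes raised exactly 2-fold 0% were called, and of those lowered 2-fold 96%, because scaling to the total shifts every ratio down slightly. None of 4969 unchanged genes was called, and 95.0% of their intervals held the true ratio. The simulated libraries shared the steady-state profile apart from the changed genes, and they had counting noise only. These rates therefore do not cover differences between animals, genotypes, gates or class make-up. Of 200 random lists, 6% fell outside the central 95%. A list of 16 genes raised 2-fold had a median of 0.92. Thinning brought shares of 68.8 and 38.7% in simulated sets of different depth to 25.7 and 25.8%, where 25.9% was true.

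Alternatives covered the cell filter, doublet removal, clustering resolution, centring of libraries, the genes used for clustering, scaling by TMM or by the median of ratios, a mean over cells, thinning, the CPM minimum, the reference library, equal class shares, and the thresholds for shares. They were fixed before the data were examined except 3, which were added later. Chosen after the data had been seen were also the yardstick for a list median under an alternative (0.5 of the width of the range of random lists), the results counted as leading ones, the bounds of the technical tests, the 90% limit for day 11 clusters and the comparison within cluster 9. The reads themselves were not used here. RNA velocity, trajectories and ligand-receptor scores were left out because 1 library per group gives them no yardstick.

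The software was Python 3.11.15 with scanpy 1.11.5 (Scrublet included), anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM.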

Results

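Single-cell RNA was counted in 3 libraries of cells sorted from mouse hearts. The first held macrophages of uninjured hearts (steady state) and the second held macrophages taken 11 days after myocardial infarction. Both came from mice that carry CreER and YFP at the Cx3cr1 locus and a Cre-dependent tdTomato at Rosa26, a pair of alleles used to label resident macrophages. The third held macrophages and dendritic cells (DCs) of uninjured wild-type hearts and served here as a second steady-state reference. Macrophages were sorted as live CD45+CD64+CD11b+ cells and DCs as CD45+CD64−CD11c+ cells with intermediate to high MHC class II, from hearts digested in the presence of the transcription inhibitor flavopiridol. There was 1 library per group, so no difference below could be set against a spread between animals, and the intervals cover counting error only.

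The steady-state macrophage library held 1806 barcodes and 23711707 UMIs in total, with a median of 10737.5 UMIs per barcode. The day 11 library held 4697 barcodes and 45177529 UMIs, with a median of 8224. The macrophage and DC library held 1780 barcodes and 14388327 UMIs, with a median of 7164. After filtering, 1741, 4497 and 1742 cells remained in this order. Of these, 1680, 4338 and 959 fell into the clusters called the macrophage compartment below, where the median depth was 10700, 8096 and 5364 UMIs. The compartment holds the clusters named as macrophages, monocytes or cycling cells. It also holds, by default, clusters that met no marker rule, with 43.3, 62.4 and 62.7% of its cells in the same order.

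The first comparison asked which kinds of macrophage make up the compartment at steady state and after infarction. Resident-like macrophages, the cluster marked by Lyve1, Folr2, Timd4 and Vsig4, made up 37.1% of the compartment at steady state (624 cells; exact binomial 95% interval 34.8 to 39.5) and 4.10% at day 11 (178 cells; 3.53 to 4.74). They made up 16.5% (14.2 to 19.0) in the macrophage and DC library. The steady-state value is at the low end of the settings tried, which gave 35.8 to 62.5% at steady state and 3.04 to 18.9% at day 11, and 56.4% and 6.48% without doublet removal. CCR2-like macrophages and monocytes, the cells of bone marrow origin in the usual description of the heart, made up 2.20% at steady state (1.56 to 3.02), 7.35% at day 11 (6.59 to 8.17) and 15.95% in the macrophage and DC library. Other settings gave this class 0.729 to 7.52% at steady state and 5.80 to 9.71% at day 11, ranges that overlap. Cluster 4, named from the fixed Arg1 or Spp1 macrophage list by its markers Gpnmb, Ctsd, Fabp5 and Lgals3, held 711 cells of the day 11 compartment, 16.4% (15.3 to 17.5), against 5 cells (0.298%) at steady state. Interferon-response-like cells made up 2.5% (1.81 to 3.36) and 3.64% (3.10 to 4.24), and their ranges over other settings overlap as well.

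Most day 11 macrophages sat apart from both steady-state libraries. Of 25 clusters, 6 drew at least 90% of their cells from the day 11 library. Together they held 65.5% of its compartment (64.0 to 66.9) and 1.96% of the steady-state compartment. A cluster filled by 1 library can reflect that library rather than a type. Of the day 11 compartment, 62.4% met no marker rule, against 43.3% at steady state and 62.7% in the macrophage and DC library. When the clustering was repeated without the 582 genes that differed at least 2-fold between these libraries, the resident-like share was 55.5% at steady state and 9.20% at day 11. The class then still held 611 of the 624 and 163 of the 178 cells. The repeated clusters were still named with all genes, among them differing genes such as Lyve1, Folr2 and Timd4. With values centred within each library the shares were 46.2% and 18.9%, the closest of any clustering tried. Cycling-like cells made up 9.23% (7.88 to 10.7) of the compartment at steady state and 4.33% (3.75 to 4.98) at day 11. In the macrophage and DC library they made up 1.98% (1.20 to 3.08), below both. The repeated clustering gave 9.55, 4.63 and 2.28% in the same order. The CCR2-like cells of the day 11 library and of the macrophage and DC library lay mostly in different clusters, so their shares do not compare 1 population.

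The second comparison asked how the macrophage compartment as a whole differed in expression between day 11 and steady state. At day 11 the compartment carried more RNA for matrix, lipid and lysosomal genes and less for the genes of resident macrophages. Spp1, which codes for the secreted matrix protein osteopontin, was at 979 CPM (UMIs per 1000000) against 91.7 at steady state, 10.7-fold higher (exact 95% interval 10.2 to 11.2). Trem2, a lipid receptor, was at 889 against 276 CPM, 3.22-fold higher (3.13 to 3.31), and Gpnmb, a lysosomal glycoprotein, at 176 against 17.3 CPM, 10.2-fold higher (9.19 to 11.3). Lyve1, a hyaluronan receptor of resident macrophages near vessels, was at 56.7 against 399.6 CPM, 7.05-fold lower (6.73 to 7.39). By the rule that picked them, each of these genes differed at least 2-fold in the same direction from the macrophages of the DC library. Spp1 was at 35.9, Trem2 at 145, Gpnmb at 1.87 and Lyve1 at 134 CPM there.

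Among the 15 genes named in each direction, the highest ratio belonged to Saa3, an acute-phase protein, at 138 against 0.409 CPM (338-fold; 178 to 739). Arg1, the arginase of repair macrophages, was 64.8-fold higher (45.6 to 95.5). Fabp5, a fatty acid carrier, was 5.82-fold higher, the protease Mmp14 10.1-fold, the lysosomal protease Ctsd 3.78-fold and Acp5 5.31-fold. Clec4d, Syngr1, Ms4a7, Cxcr4, Olfml3 and Tmem119 were also among the higher genes, the last a gene best known from microglia at 3.03-fold. Retnla, a secreted protein of macrophages exposed to type 2 cytokines, was the lowest by both references, at 61.5 CPM against 1127 at steady state (18.3-fold lower; 17.6 to 19.1) and 8351 in the DC library's macrophages, where cluster 12, almost absent from the other libraries, held most of it. The lectin Mgl2 was 4.85-fold lower, the eosinophil chemoattractant Ccl24 6.97-fold, the haemoglobin scavenger receptor Cd163 5.02-fold, the lipid receptor Cd36 3.56-fold and the growth factor receptor Fgfr1 6.11-fold. Hspb1, Xlr, Dok2, Mmp13, Pilrb1, Lyz1, Eps8 and Fxyd2 were the other lower genes.

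The genes located here are protein coding. In the mm10 build, Spp1 (ENSMUSG00000029304) lies on chromosome 5 from 104435118 to 104441050 and Trem2 (ENSMUSG00000023992) on chromosome 17 from 48346401 to 48354147. Gpnmb (ENSMUSG00000029816) lies on chromosome 6 from 49036546 to 49070929, and Lyve1 (ENSMUSG00000030787) on chromosome 7 from 110850607 to 110863239. Retnla (ENSMUSG00000061100) lies on chromosome 16 from 48842551 to 48844461, and Timd4 (ENSMUSG00000055546) on chromosome 11 from 46810800 to 46844332.

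The fixed gene lists gave the same picture by function. Of 16 measured resident macrophage genes, 11 were at least 2-fold lower at day 11 and none was 2-fold higher, with a median log2 ratio of −1.87, below all 10000 random lists of equal size and expression. Timd4, a receptor for dying cells, was 7.79-fold lower and Folr2 4.06-fold lower, whereas the growth factor Igf1 was at 287 against 248 CPM, a ratio of 1.16. Of 11 measured matrix and remodelling genes, 6 were at least 2-fold higher and 2 lower, with a median of 1.83. Thbs1 was 20.2-fold and Fn1 11.1-fold higher, while Mmp9 was 13.2-fold lower. The lipid and lysosome list had a median of 0.84, with 8 of 20 genes at least 2-fold higher. Among them were Ctsd, Cd9 at 2.92-fold and Lgals3 at 2.44-fold, whereas Cd36, also a member, was more than 2-fold lower, as given above. Apoe, the most abundant member, was at 41179 against 20861 CPM, a ratio of 1.97.

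Inflammatory genes differed less. The list of inflammatory cytokines and chemokines had a median of 0.35, with 3 of 12 genes at least 2-fold higher and none lower. The chemokine Ccl8 was 2.37-fold higher, Il1b was at 215 against 92.0 CPM and Cxcl16 was 2.16-fold higher. Monocyte genes had a median of 0.38, led by Thbs1, Fn1 and Hp, while Ccr2 itself was at 248 against 175 CPM, a ratio of 1.42. Without cluster 14, whose steady-state cells also carried macrophage RNA, the monocyte median was 1.09. Glycolysis genes had a median of 0.22 and none of the 15 differed 2-fold. Cell cycle genes had a median of −0.66, with Mki67 at 23.1 against 40.2 CPM and Top2a at 30.8 against 52.7 CPM. Lower medians, which need not hold for every member, were found for 3 lists. These were immediate early genes (−0.39, with Klf2 3.83-fold and Klf4 2.52-fold lower), heat shock genes (−0.38, with Hspa1b 3.26-fold lower) and iron handling genes (−0.21, with the exporter Slc40a1 2.81-fold lower). MHC class II (−0.16), MHC class I (−0.02), the type I interferon response (−0.12), anti-inflammatory genes (−0.02), phagocytosis receptors (−0.10), complement (−0.08) and oxidative phosphorylation (0.08) lay inside the range of random lists, and no direction is read from them. The median of all 5320 genes above the minimum was −0.06.

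**Figure D1:**
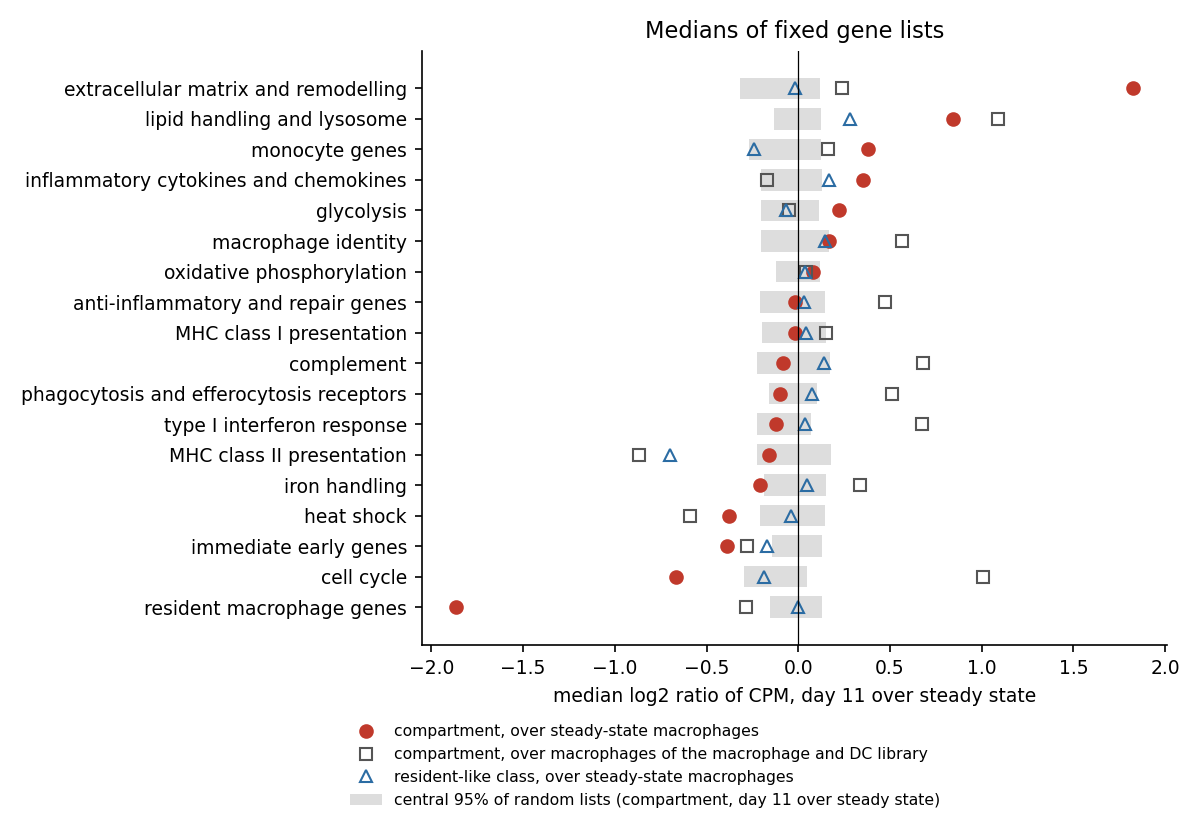
Median log2 ratio of CPM (horizontal axis) of each fixed gene list (vertical axis), day 11 over steady state, for the macrophage compartment against each steady-state library and for the resident-like class; the grey bar is the central 95% of random lists. Resident macrophage genes sit at −1.87 in the compartment against the steady-state macrophage library and matrix genes at 1.83.

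Some list directions held against only 1 of the 2 steady-state libraries. Against the macrophages of the DC library, the cell cycle median was 1.01, the inflammatory median −0.17, glycolysis −0.05 and iron handling 0.34, each opposite in sign. The median of all genes was 0.21 against this reference. The lipid and lysosome list (1.09) kept its direction and the resident list (−0.28) kept it at a smaller size, while monocyte genes (0.16) and matrix genes (0.24) lay inside the range of random lists. These values depend on cluster 12, almost all of whose cells came from this library. Without it in the reference the medians were 0.63 for the cell cycle, −0.56 for inflammatory, 0.16 for iron, −0.71 for resident and 1.53 for matrix genes. The steady-state libraries also differed from each other. Over the steady-state macrophage library, the DC library's macrophages had a median of −1.26 for resident genes, −1.55 for the cell cycle and 0.71 for MHC class II. These libraries differ in genotype and gate. List differences were smaller with class make-up held equal. The ratios within 7 classes and clusters were averaged by their steady-state sizes, which leaves out most clusters filled by day 11 cells. The medians were then −0.37 for resident, 0.30 for lipid and lysosome, 0.085 for monocyte and 0.052 for matrix genes. Genes of these lists are also among the markers that named classes, which can shrink ratios within a class.

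The third comparison asked whether macrophages of 1 class also differed between day 11 and steady state, apart from the class make-up of the compartment. A different mix of cells inside a class is not separated by these ratios. This holds above all for the cycling-like and interferon-response-like classes, whose markers name a program. Resident-like cells at day 11 carried more RNA for Ccl8, a chemokine for CCR2 and other receptors, at 790.5 against 205 CPM (3.86-fold; 3.58 to 4.17). They also carried more Spp1, 94.9 against 33.6 CPM (2.83-fold; 2.29 to 3.47), and more Trem2, 586 against 290 CPM (2.02-fold; 1.87 to 2.18), with the lectin Clec4n 2.18-fold higher. Retnla was at 325 against 1836 CPM, 5.64-fold lower (5.16 to 6.18). In endothelial-like cells, which should lack Spp1, it was at 135 CPM at day 11 (11 cells) and 11.6 CPM at steady state, so the Spp1 level in resident-like cells was not above that background. Ccl8 was at 33.8 CPM in the same endothelial-like cells at day 11, and Trem2 at 186 CPM, from 1 of the 11. Trem2 was also at 236 CPM in cDC2-like cells of day 11, so its 2.02-fold difference is not clear of background.

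MHC class II genes were lower in resident-like cells at day 11, with a median log2 ratio of −0.70 over 8 genes, below all random lists, and none reached 2-fold. H2-Ab1, a chain of the class II molecule, was at 3200 against 5499 CPM, and the transcriptional activator Ciita had a ratio of 0.617. H2-Ab1 in endothelial-like cells was at 794 CPM at day 11 and 1914 at steady state. Against the DC library's resident-like cells the median was −0.91. The resident list had a median of −0.00 within the class, which the class assignment by these same genes favours.

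CCR2-like cells at day 11 carried more RNA for Il1b, Ctsl and Clec4n and less for Retnla, Hspa1a and Cxcl10, while the inflammatory list as a whole had a median of −0.58. The cytokine Il1b was at 692 against 82.9 CPM, 8.34-fold higher, the lysosomal protease Ctsl at 722 against 104 CPM (6.97-fold; 5.19 to 9.57) and the lectin Clec4n at 893 against 161 CPM (5.54-fold; 4.37 to 7.13). Retnla was 17.9-fold lower (15.4 to 20.8), Hspa1a 3.45-fold (2.98 to 3.99) and the interferon-induced chemokine Cxcl10 3.74-fold (2.95 to 4.71). These intervals count UMIs and leave out differences between cells, of which the steady-state side had 37. Of 11 matrix genes, 7 were at least 2-fold higher and none lower, with a median of 1.71. Hypoxia response genes had a median of 0.84 with 4 of 8 at least 2-fold higher, and glycolysis genes one of 0.46. The class had 37 cells at steady state and 319 at day 11, of which 178 lay in a day 11 cluster marked by Arg1, Cxcl3, Spp1, Fn1 and Thbs1.

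That cluster set part of these values. In cluster 9, the CCR2-like cluster present in all 3 libraries, compared after its values were seen (27 steady-state and 141 day 11 cells), Il1b was 6.64-fold higher (4.26 to 11.0), Ctsl 6.17-fold (3.40 to 12.5) and Clec4n 4.18-fold (2.60 to 7.14). Retnla was 9.62-fold lower (8.24 to 11.3) and Cxcl10 2.39-fold lower (1.86 to 3.05) there. Arg1 was 26.1-fold higher in the class but at 17.8 against 3.39 CPM in cluster 9, where the interval of the ratio (0.851 to 215.8) includes no difference. Fn1 was 4.77-fold higher in the class and 1.95-fold in cluster 9.

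Cycling-like macrophages carried more RNA for Fn1 and Saa3 at day 11 and less for Retnla and resident genes. Fn1 was 9.86-fold higher at day 11 (7.16 to 13.9) and Clec4d 9.28-fold, while Saa3 was at 184 CPM against no UMI, at least 169-fold higher at the 3-count floor. Spp1, at 398 CPM at day 11, was not clear of its background, which reached 564 CPM in T or NK-like cells. Retnla was 33.0-fold lower (24.5 to 45.6), Timd4 5.18-fold (3.71 to 7.41), Lyve1 3.74-fold and Cd163 3.73-fold. Of 16 resident genes, 10 were at least 2-fold lower. The 25 cell cycle genes had a median of 0.36 within this class and none differed 2-fold.

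Interferon-response-like cells at day 11 carried more RNA for monocyte genes, with 8 of 11 at least 2-fold higher and a median of 1.87. Ly6c2, a marker of classical monocytes, was 8.06-fold higher (4.17 to 17.9), Ccl5 27.1-fold (13.1 to 67.7) and Ly6a 17.2-fold. Their interferon list itself had a median of 0.41. Lyve1 was 9.91-fold lower (7.11 to 14.04) and Pla2g2d 10.8-fold. This class had 42 cells at steady state and 158 at day 11. In the unnamed cluster 0, the largest steady-state cluster besides the resident-like one at 34.3% of the compartment, Olfml3 was 2.03-fold higher and Retnla 17.4-fold lower. In the unnamed cluster 2, Apoe was 2.02-fold and Ctsd 2.45-fold higher, and Mmp12 4.92-fold lower. Spp1 in these clusters, at 114 and 187 CPM at day 11, was not clear of its background.

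The shares of compartment cells with a UMI of a marker, in cells thinned to 3000 UMIs, do not use the classes within the compartment. Timd4 was found in 25.3% of compartment cells at steady state (23.2 to 27.4), 3.38% at day 11 (2.86 to 3.97) and 10.5% in the DC library, and without thinning in 55.9, 7.42 and 14.7%. Lyve1 was found in 47.1% (44.7 to 49.5), 7.82% (7.03 to 8.66) and 17.4%, and without thinning in 69.7, 12.8 and 19.2%. The background was not low at steady state: in DC-like and lymphoid cells of that library (48 cells, median depth 16527.5 UMIs), Timd4 was found in 16.7% and Lyve1 in 29.2%. In endothelial-like cells (11 cells, median 5625), Timd4 was found in 0, which allows up to 28.5%, and Lyve1 in 9.09%. In DC-like and lymphoid cells of the day 11 library Lyve1 was found in 3.65%. Arg1 was found in 0.179% at steady state and 7.02% at day 11 (0.536 and 12.7% without thinning), and in 2.19% of DC-like and lymphoid cells at day 11.

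Ccr2 was found in 27.5% of compartment cells at steady state, 34.8% at day 11 and 45.6% in the DC library when thinned, and in 47.4, 49.5 and 49.8% without thinning. Cx3cr1, the fractalkine receptor, was found in 41.5, 43.8 and 33.0% when thinned and in 73.6, 70.5 and 46.7% without thinning. In endothelial-like cells of the steady-state library, Ccr2 and Cx3cr1 were each found in 1 of 11. H2-Ab1 was found in 99.8, 94.98 and 99.5% of thinned compartment cells, but also in all 11 of these endothelial-like cells, so its share tells nothing here. Isg15 was found in 18.1, 12.9 and 10.4% when thinned, while its level in the compartment was 78.9, 83.0 and 70.4 CPM, so no order is read from its shares.

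**Figure D2:**
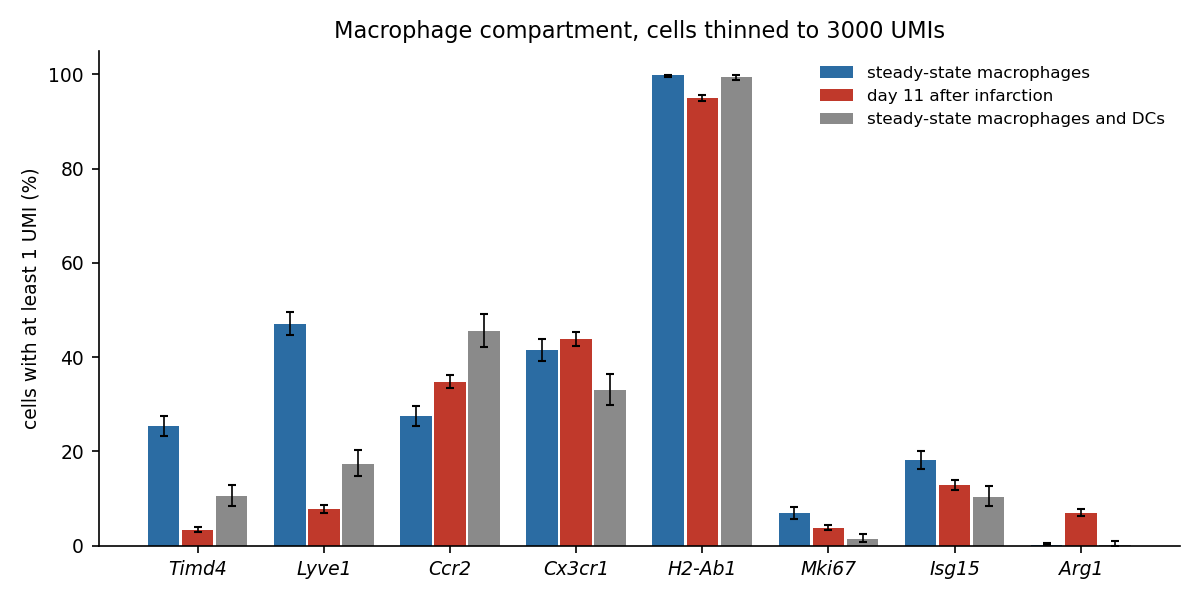
Share of macrophage compartment cells with at least 1 UMI of each of 8 marker genes (vertical axis, percent; horizontal axis, gene) in the 3 libraries, in cells thinned to 3000 UMIs; bars are shares and error bars exact binomial 95% intervals. Timd4 is at 25.3% at steady state and 3.38% at day 11.

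Proliferation was measured because the series title names self-renewal. Cells with UMIs of at least 3 of 25 cell cycle genes, after thinning, made up 9.76% of the compartment at steady state (164 of 1680 cells; 8.38 to 11.3) and 4.88% at day 11 (208 of 4261; 4.25 to 5.57). In the DC library they made up 2.72% (22 of 809; 1.71 to 4.09), below both. Mki67, the usual marker of dividing cells, was found in 6.85, 3.85 and 1.48% in the same order, and without thinning in 15.6, 7.84 and 3.13%. DC-like and lymphoid cells, which can divide themselves, were at 8.33, 3.65 and 14.4% in the same order, and 0 of 11 steady-state endothelial-like cells passed. Without thinning the compartment shares were 32.6, 9.77 and 4.38%, so the measure depends on depth.

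The reporter comparison asked how much reporter RNA was found in the macrophages of the reporter mice in each state. TdTomato RNA was found in 12.98% of compartment cells at steady state (218 of 1680; 11.4 to 14.7) and in 1.41% at day 11 (61 of 4338; 1.08 to 1.80). Its level was 13.4 against 1.58 CPM, 8.46-fold lower at day 11 (6.44 to 11.3). These levels rest on 295 and 64 UMIs, fewer than the cells in each library, so a labelled cell can lack a UMI. The shares given here are therefore not shares of labelled cells. In resident-like cells the shares were 12.7% (10.2 to 15.5) and 3.93% (1.60 to 7.93), in cycling-like cells 13.5% and 3.72%, and in cluster 0 14.1% and 2.74%. In CCR2-like cells no steady-state cell of 37 had a TdTomato UMI, which allows up to 9.49%, and 0.313% of day 11 cells did. Cells of cluster 4, the Gpnmb-marked cluster of day 11, were at 0.281%.

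The background share for TdTomato was as high as the compartment's at steady state in 1 set of cells. Among DC-like and lymphoid cells, 7 of 48 (14.6%) had a UMI there, clusters that also carried macrophage RNA such as C1qa, at 6177 CPM in B-cell-like cells, whereas 0 of 11 endothelial-like cells had one. At day 11, 1 of 142 DC-like and lymphoid cells (0.704%) had a UMI. EYFP RNA, read from the Cx3cr1 locus itself, was found in 39.2% (36.9 to 41.6) and 24.99% (23.7 to 26.3), at 47.5 against 35.7 CPM, a ratio of 1.33 for steady state over day 11 (1.23 to 1.44). DC-like and lymphoid cells had an EYFP UMI in 29.2% (14 of 48) at steady state and 21.8% (31 of 142) at day 11, close to the day 11 compartment, and no endothelial-like cell of either library had one. CreERT2 was at 1.04 against 0.594 CPM, with a ratio of 1.76 whose interval, 0.949 to 3.25, includes no difference. The labels give no tamoxifen schedule, so a share with TdTomato RNA is not a share of cells of any origin.

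**Figure D3:**
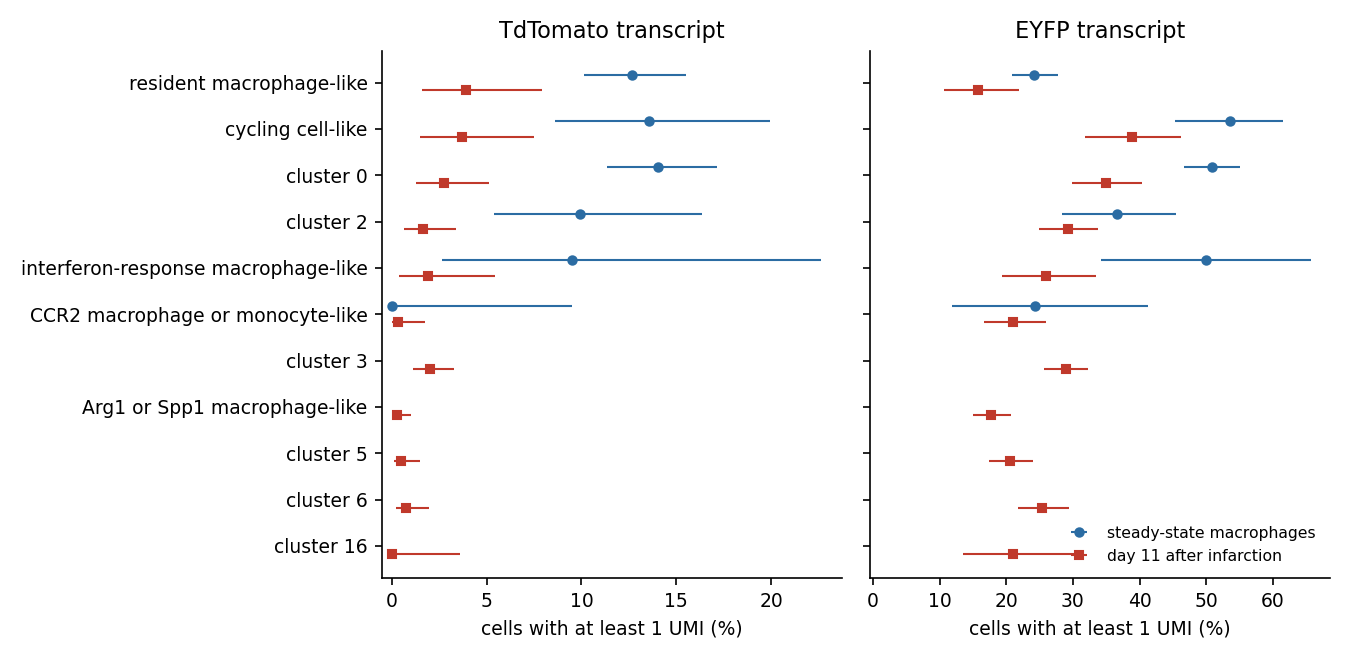
Share of cells with at least 1 UMI of TdTomato or EYFP (percent axis) by class or cluster, with steady state as circles and day 11 as squares and exact binomial 95% intervals as bars, for groups of at least 30 cells. TdTomato in resident-like cells is at 12.7% and 3.93%.

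The last comparison set DCs against macrophages of the same uninjured hearts, within the macrophage and DC library. Conventional type 1 DCs (cDC1-like, 279 cells, 16.02% of the library's cells), named by their DC markers, carried hardly any of the macrophage program. Type 2 DCs (cDC2-like, 345 cells, 19.8%) carried more macrophage RNA. The sort gates set these shares. The compartment used as the reference here had 959 cells, of which 189 were of cluster 12. The macrophage identity list had a median log2 ratio to the compartment's macrophages of −5.22 in cDC1-like cells, with 8 of 9 genes at least 2-fold lower, and −2.56 in cDC2-like cells, with 7 of 9. Csf1r, the receptor macrophages need to survive, was at 16.02 CPM in cDC1-like, 107 in cDC2-like cells and 633 in macrophages. C1qa, a complement component made by macrophages, was 59.5-fold lower in cDC1-like cells and 36.3-fold lower in cDC2-like cells.

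Complement as a list was lower in both DC kinds, with medians of −5.25 and −4.45, as were lipid and lysosome genes at −3.21 and −1.87. Inflammatory genes had medians of −4.27 and −3.53, with 12 of 12 and 11 of 12 at least 2-fold lower. The DC growth factor receptor Flt3 was 31.9-fold higher in cDC1-like cells. The MHC class II list lay close to the compartment as a whole in cDC1-like cells, with a median of 0.08. It was higher in cDC2-like cells at 0.48, where H2-DMb2 and H2-Oa of the list are also naming markers. The compartment itself was mixed for this list. Over the whole, resident-like cells were at −1.22, cluster 0 at −0.34, cluster 12 at 0.11 and cluster 2 at 0.47. H2-Oa, which restrains peptide loading, was 19.4-fold higher in cDC1-like cells. In the 18 mature DC-like cells MHC class I genes had a median of 1.51, with 8 of 12 at least 2-fold higher, and H2-Ab1 was 2.10-fold lower. Genes that name these classes, such as Xcr1, Cd209a and Ccr7, are not results here.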

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

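All technical tests in this part were chosen after the result was seen. One result called for a closer look because the same list moved in opposite directions in separate cell classes. Inflammatory cytokine and chemokine genes had a median log2 ratio, day 11 over steady state, of 0.81 in interferon-response-like cells and of −0.58 in CCR2-like cells. In interferon-response-like cells, 4 of 13 measured genes were at least 2-fold higher and none lower, with Ccl8 4.52-fold, Ccl7 3.22-fold and Il1b 2.16-fold higher. In CCR2-like cells, 4 of 14 were at least 2-fold lower, Cxcl9 7.22-fold, Cxcl10 3.74-fold, Ccl2 3.40-fold and Ccl12 3.03-fold, while 3 were higher, led by Il1b at 8.34-fold. The difference between the classes was not tested, since each group has 1 library, and it rests on 42 and 37 steady-state cells. The CCR2-like class also differs in its clusters, since 178 of its 319 day 11 cells lay in a day 11 cluster. In cluster 9, which all libraries share, Cxcl10 was 2.39-fold lower and Il1b 6.64-fold higher.

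TdTomato RNA was found in fewer macrophages at day 11 than at steady state. The tables argue against lower depth, because the CPM ratio was 8.46 (6.44 to 11.3), and against class make-up alone, because in clusters with at least 30 steady-state cells (1353 day 11 cells) the steady-state shares would give 12.2% where 2.66% was found (1.87 to 3.66), or 11.9% and 2.58% without cluster 14. Free RNA in the steady-state library stays open, because 7 of 61 cells outside the compartment (11.5%; 4.74 to 22.2) had a UMI, an interval that includes the compartment's share, though 0 of 37 CCR2-like cells had one. Entry of cells without the label may explain the pattern and stays open as an untested hypothesis, as do the labelling schedule, which the labels do not give, and a difference in labelling between animals.

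Retnla was lower at day 11 in the compartment and in each class compared. Free RNA alone is argued against, because 12.7% of resident-like cells, thinned to 3000 UMIs, had at least 10 Retnla UMIs at steady state (10.2 to 15.5) and 2.86% at day 11 (0.934 to 6.54). Different shares of the named classes alone are argued against by the ratio within resident-like cells, 0.177 (0.162 to 0.194). Fewer Retnla-rich cells inside that class would give the same ratio, so make-up within the class stays open. In the whole libraries, the 5% of barcodes richest in Retnla held 62.8% of its UMIs at steady state and 96.0% at day 11. Free Retnla RNA was nevertheless present at steady state, at 371 CPM in endothelial-like cells with a UMI in 10 of 11 against 0 of 11 at day 11, and the 316 CPM of the steady-state cluster 2 did not exceed it. A lower Retnla level in macrophages after infarction may be a biological difference, and a difference between animals or in cell handling stays open because each group has 1 library.

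Macrophage RNA appeared in clusters of other cells of the steady-state library, with C1qa at 5477 CPM in the cluster of non-classical-like monocytes and 6177 CPM in B-cell-like cells. Free RNA at an even level is argued against, because C1qa in the monocyte-like cluster was 5.76 times that of endothelial-like cells (4.63 to 7.25). Droplets holding a pair of cells could be part of the source: the median depth was 18739 and 16431.5 UMIs in these clusters against 10700 in the compartment, and the smaller ratio of 1.54 met the prediction. These clusters held 90 and 28 cells, though, more than the 26 doublets that the assumed rate gave for the whole library, a number already removed. Chance doublets at that rate would therefore not supply them all. The same monocyte-like cluster had a median of 3630 UMIs and C1qa at 31.9 CPM in the macrophage and DC library, but at day 11 a median of 9125 UMIs, 1.13 times the compartment's, with C1qa at 4383 CPM, so depth gives no such sign there. No biological explanation was tested, and the monocyte-like cluster is not compared as a class, though it is part of the compartment and of averages over classes.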

How the results depend on the processing

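Most alternatives were fixed before the data were examined. The DC-library reference without cluster 12, the compartment without cluster 14 and the compartment without the barcode richest in haemoglobin RNA were chosen after seeing the data. No paired analysis was possible because each group had 1 library. A value counted as moved when it left its 95% interval, or, for a list median, when it shifted by more than 0.5 of the width of the random-list range. The cause was not tested for any value below.

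The 30 genes named for the compartment gave 510 values under 17 alternatives. All kept their direction, and 335 stayed close while 175 moved. For the DC-library reference that direction was fixed in advance by the rule that picked the genes. The alternatives added 1 CPM to both sides of a gene's ratio, which the main ratios did not. Genes of low CPM could move for that reason alone. The log2 ratios of Saa3 and Arg1 reached at most 7.12 and 5.40, below their main intervals under every alternative. The minimum of 5 CPM cannot change a gene's ratio. Scaling by TMM or by the median of ratios shifts ratios too little to turn a 2-fold gene. Log2 ratios ranged from 1.56 to 4.73 for Spp1, from −7.06 to −3.46 for Retnla and from −2.91 to −1.05 for Lyve1. Of 306 list medians, 8 reversed, counting only lists whose median lay outside the random-list range. Among the other lists, against the DC library's macrophages, complement was at 0.68, the interferon response at 0.67, phagocytosis receptors at 0.51, anti-inflammatory genes at 0.47 and MHC class II at −0.87, and MHC class I reached 0.15.

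The resident-like share stayed higher at steady state than at day 11 under every alternative, from 35.8 to 62.5% against 3.04 to 18.9%. With at least 200 genes and at most 20% mitochondrial UMIs it was 62.5 and 8.11%, and the day 11 cycling-like share was 5.68%. With at least 1000 genes and at most 5%, resident-like shares were 54.4 and 5.55% and cycling-like shares 7.30 and 3.56%, and no non-classical-like class was named. Without doublet removal they were 56.4 and 6.48%, and with the automatic Scrublet threshold 57.2 and 6.59%. At resolution 0.5 the steady-state share was 44.2%. At resolution 2.0 the day 11 resident-like and cycling-like shares were 3.04 and 3.70%. Centring within libraries gave 46.2 and 18.9%, and clustering without differing genes 55.5 and 9.20%. Expression within a class was not recomputed under these alternatives, although the cells of the classes changed.

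Scaling by TMM shifted every log2 ratio by 0.13 and by the median of ratios by 0.14, which took the median of all genes from −0.06 to 0.08. The lipid and lysosome median was then 0.97 and 0.98. Thinned cells gave a monocyte median of 0.59, a minimum of 5 CPM a matrix median of 1.42, and leaving out cluster 14 a monocyte median of 1.09.

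The reference mattered more. Against the macrophages of the DC library, the cell cycle (1.01), inflammatory (−0.17), glycolysis (−0.048) and iron (0.34) medians reversed. The resident median was −0.28, monocyte 0.16, matrix 0.24 and lipid 1.09. Without cluster 12 in that reference, the cell cycle (0.63), inflammatory (−0.56) and iron (0.16) medians were also reversed, while resident genes were at −0.71, monocyte genes at 0.083, matrix genes at 1.53 and lipid genes at 1.00. With class shares held equal, by averaging the ratios within classes by steady-state size, medians were nearer 0: resident −0.37, monocyte 0.085, matrix 0.052 and lipid 0.30, and iron reversed to 0.0022. That average leaves out most clusters filled by day 11 cells. Genes of these lists also helped to name classes, which can shrink the ratios within them.

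Shares of cells depend on depth. Without thinning, thinned to 1500 UMIs, and with at least 2 UMIs required, Timd4 shares were 55.9, 15.4 and 6.67% at steady state and 7.42, 1.36 and 0.634% at day 11. Lyve1 shares were 69.7, 33.7 and 27.2% against 12.8, 4.79 and 3.36%. Cycling shares with 2 genes, 5 genes and without thinning were 16.5, 7.68 and 32.6% against 7.67, 3.78 and 9.77%. TdTomato shares with at least 2 UMIs and with thinning were 2.08 and 4.23% against 0.0692 and 0.422%. In each of these pairs steady state was higher. Of 106 class shares 42 moved, and of 93 cell shares 85 moved. The 37 CCR2-like cells at steady state limit what that class can show.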

Other observations

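The macrophage sorts also caught DC-like cells, although the gate required CD64. There were 109 cDC2-like cells in the day 11 library and 15 at steady state, and H2-Ab1 was at 20310 CPM in those of day 11 against 21375 CPM in the cDC2-like cells of the macrophage and DC library. Their C1qa level was 2333 CPM at day 11 against 119 CPM in that library, and their Trem2 level 236 against 6.36 CPM. These cells lay mostly in different clusters, 97 of the 109 in cluster 15 and 342 of the 345 of the other library in cluster 8, so they do not compare 1 population. B-cell-like cells numbered 28 at steady state and 13 at day 11, T or NK-like cells 4 and 17, endothelial-like cells 11 and 11, and fibroblast-like cells 2 and 6. The macrophage and DC library held 55 and 44 cells in a pair of cycling clusters set outside the compartment, whose DC markers were raised as a set, those of cDC1 in the first and of cDC2 in the second.

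Cluster 12 took 189 of its 195 cells from the macrophage and DC library, where it made up 19.7% of the compartment. It met no marker rule. Its cells had Csf1r at 294 CPM against 633 in the library's whole compartment, C1qa 3.12-fold lower and Fcgr1, which codes for CD64, at 11.6 against 114 CPM, while Flt3 was at 0.551 CPM and no Zbtb46 UMI was found. Whether these cells came through the CD64-negative gate was not recorded. Retnla in the compartment of that library (8351 CPM) rests largely on this cluster, at 24618 CPM.

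Cardiomyocyte RNA was lower at day 11 in the compartment, with a median log2 ratio of −1.30 over 3 measured genes, Tnni3 at 6.63 against 22.6 CPM, Myl2 at 14.8 against 38.1 CPM and Mb at 9.85 against 25.3 CPM. In the macrophage and DC library, 42 cells carried both cDC1 and cardiomyocyte markers. The erythrocyte list had a median of −5.55 that rests on 1 steady-state barcode, which held 3465 of the 3786 Hbb-bs UMIs of the compartment. Without it Hbb-bs was at 14.6 instead of 172 CPM at steady state, against 1.04 CPM at day 11. Neutrophil genes (−1.21), macrophage identity genes (0.17), DC identity genes (0.23), hypoxia genes (0.37), fibroblast genes (0.29) and lymphocyte genes (0.14) rest on 2, 10, 3, 4, 1 and 1 measured members, and no endothelial gene reached the minimum.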
